A study of Mus musculus with 24 samples.

How the data were processed

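Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed for CTCF, the cohesin subunit SMC1 and the Mediator subunit MED1 in WT-1 cells, a mouse brown preadipocyte line differentiated in culture. Per the labels' protocols, lentivirus carrying a non-targeting shRNA (control) or an shRNA against H2A.Z (knockdown, KD) was added on day 6, and the cells received vehicle or the β3-adrenergic agonist CL316,243 for 4 h on day 11. CTCF chromatin was fixed with formaldehyde alone and SMC1 and MED1 chromatin with DSG and formaldehyde, so numbers of peaks were not compared between factors. The series held 24 samples, of which 14 ChIP libraries had a peak list and 10 were inputs without one. The 14 libraries formed 7 groups with 2 replicates each. Nothing in the labels says that the replicates came from separate cultures, so the spread between them may be technical.

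For 8 samples, 5 of them ChIP libraries, the genotype or treatment characteristic contradicted the title. Titles were used, since the library names, the series design text and the names in the file headers all matched them. The ChIP libraries in doubt are all 4 of SMC1 and MED1 stimulated control replicate 1. By the characteristics, the SMC1 libraries titled vehicle would be stimulated control cells, those titled stimulated would be stimulated KD cells, and the MED1 library would be vehicle-treated. The SMC1 and MED1 comparisons therefore rest on the titles, whereas no CTCF library is in doubt.

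Peaks were called by the authors in each library separately, against an input, with MACS 2.2.7.1 in paired-end mode at a q-value threshold of 0.01 and an effective genome size of 1870000000, keeping 1 fragment per position, per the file headers. The SMC1 and MED1 control libraries of the same treatment and replicate number shared 1 input library, per the file headers. The genome build was mm10 and deepTools 3.3.1 was also named, per the submitters' processing notes. The aligner is not given in the sources used here. Each deposited peak carries a pileup, which is a coverage signal at the summit, per the file headers. It also carries a fold enrichment over input, a linear ratio, per the file headers. The remaining deposited values are the −log10 p-value and the −log10 q-value of each peak, per the file headers. These scores are the authors' own and served only to rank or filter peaks within a list.

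Fragments after filtering ranged from 14503559 to 25963214 per ChIP library. A peak missing from a list can reflect lower depth or enrichment as well as lower occupancy, so regions are described as called or not called. Peaks on chromosomes 1 to 19, X and Y were used, which left out 6 peaks. All peaks of a factor were merged where they shared at least 1 bp, and a library was said to call a region when 1 of its peaks lay in it. A region was gained when both libraries of the first group and neither of the second called it, and lost in the reverse case. With 2 libraries against 2 there are 3 splits, so an exact permutation test cannot give a two-sided p under 0.333, and the counts were set beside those of the other 2 splits.

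Overlap between factors was compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the tests of each family. Shares within a group are over regions merged from its libraries and called in both. Gained or lost regions were set against regions called in all 4 libraries, and counted as carrying another factor where they met a region called in both of its libraries. Where gained or lost MED1 regions were set beside gained or lost SMC1 regions, the reference was all other MED1 regions called in 2 or more of the 4 libraries, in whichever group. Regions are not replicates, and neighbouring regions are not independent, so these p-values describe these libraries only. MED1 calls in KD cells were compared with a two-sided permutation test within 10 classes of strength, the mean percentile of −log10 q in the stimulated control lists, with 100000 resamples. Regions were assigned to the nearest protein-coding gene span within 100 kb, using 21887 genes of GRCm38.p6, the assembly that mm10 names. The 14 gene lists held 401 symbols, all of which matched. They were thermogenic program, cAMP and beta-adrenergic response, lipolysis and fatty acid oxidation, adipocyte identity and lipogenesis, oxidative phosphorylation, glucose and glycolysis, circadian clock, chromatin looping with Mediator and H2A.Z machinery, inflammatory response, preadipocyte and fibroblast markers, macrophage markers, skeletal muscle lineage markers, neuronal genes and housekeeping genes. Each was tested against 100000 random gene sets matched on regions per gene, two-sided, with Benjamini-Hochberg adjustment over 112 tests.

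The groups, tests, lists and other settings to be tried were fixed before the data were examined. The analysis departed from these plans as follows. The gene table gives no strand or exons, so the planned nearest transcription start site became the nearest gene span, and promoter, exon and intron classes became within 1 kb of either gene end, inside a span or between genes. Motifs were not analysed here, since no genome sequence was used. The planned 50% overlap rule moves nothing within a factor, because each peak lies inside its merged region, and a rule that peaks cover 50% of the region was added after seeing the data.

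Named genes followed a fixed rule. For each comparison it took 11 genes of interest, the 10 genes of the thermogenic and cAMP lists with the most gained plus lost regions, the 5 gained and 5 lost regions of highest mean strength percentile, and the 5 densest MED1 clusters per group, joined within 12 kb. Genes chosen after their values were seen are said to be so. Alternatives were −log10 q of at least 3 or 5, lists cut to equal length, summit windows of 250 bp on each side, other gene distances, leaving out each replicate, and fits within each replicate number.

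The procedures were tested on simulated data. For MED1, stimulated against vehicle, 200 of 200 planted gained regions were recovered among 21603. Recovery was close to certain by design, since these regions were planted in every library of 1 group and none of the other. Another 51 MED1 regions that were not planted were also classed as gained, against 161 for SMC1 and 131 for CTCF. The list test called 8 of 200 random lists at 0.05 and all 200 lists with a rate 2.5 times that of the rest, over 5851 genes. For SMC1 it called 152 of 200 such lists, over 14777 genes, and for CTCF 84 of 200, over 14938. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.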

Results

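Occupancy of CTCF, SMC1 and MED1 was mapped in differentiated WT-1 brown adipocytes to ask where architectural proteins and Mediator sit before and after acute β3-adrenergic stimulation, and how Mediator is placed when the histone variant H2A.Z is depleted. CTCF binds DNA directly and marks many loop anchors, SMC1 is part of the cohesin ring, and MED1 belongs to the Mediator complex that links enhancers to RNA polymerase II. CTCF and SMC1 were profiled in control cells given vehicle or agonist, and MED1 in those groups and in stimulated H2A.Z KD cells, with 2 libraries per group. H2A.Z itself was not measured in these libraries, so its depletion is not shown here. CTCF libraries held 16222468 to 24120395 fragments, SMC1 libraries 14503559 to 25963214 and MED1 libraries 16033515 to 19633715.

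MED1 was called at more regions after stimulation in the lists as deposited, and the added regions included several at genes of cAMP signalling. The genes below were picked from the thermogenic and cAMP lists for their many gained plus lost regions, so their presence shows no preference. The cAMP list as a whole did not pass after adjustment (permutation test, adjusted p = 0.125). Pde4d, which encodes a phosphodiesterase that degrades cAMP, had 10 gained MED1 regions and none lost, all inside its span on chromosome 13. Irs2, an insulin receptor substrate, had 5 gained regions, and Sik1 (a salt-inducible kinase), Pde4b (another cAMP phosphodiesterase) and Cebpb (an adipogenic transcription factor) had 4 each. Adcy3, an adenylyl cyclase, had 3, among them the region of the second-highest mean strength of all gained regions, at chromosome 12, 4162577 to 4163505, inside the gene. Nr4a1, Gadd45g, Irf4 and Ppargc1a, the last a coactivator of mitochondrial biogenesis, had 2 each. Gained regions made up 2545 of all 13344 MED1 regions called in 2 or more of the 4 libraries. By gene they made up 10 of 16 at Pde4d, 5 of 19 at Irs2, 4 of 7 at Sik1 and at Pde4b, and 4 of 16 at Cebpb. They were 3 of 5 at Adcy3, 2 of 4 at Nr4a1, 2 of 8 at Gadd45g, 2 of 2 at Irf4 and 2 of 16 at Ppargc1a.

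Genes of the brown fat program had gained, lost or shared MED1 regions. Ucp1, the uncoupling protein of brown fat, had 1 MED1 region, from 83282758 to 83293630 on chromosome 8, called in all vehicle and stimulated libraries. Elovl3, a fatty acid elongase, had 1 gained region at chromosome 19, 46109974 to 46111260, about 20.6 kb outside the gene, and Prdm16 and Adipoq had 1 gained region each. Adrb3, the receptor of the agonist, had 1 lost region, at chromosome 8, 27227361 to 27228815, inside the gene, and Pparg had 1 lost region. Cidea and Fabp4 had 3 regions each that all 4 libraries called and none gained or lost. No MED1 region was assigned to Dio2 or to the muscle gene Myod1. The gained region of Prdm16 and the lost region of Adrb3 were no longer so classed at −log10 q of 5, nor were the gained regions of Irf4 and the lost region of Pparg when peaks had to cover 50% of a region. Single regions became gained at Pparg at −log10 q of 5, at Ucp1 with 50% cover and at Adrb3 with summit windows. With equal-length lists 1 became lost at Gadd45g, and the gained regions of Cebpb numbered 2 in place of 4.

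In all, 2545 MED1 regions were gained and 353 lost, against 6232 called in all 4 libraries. The other splits of the 4 libraries gave 78 and 765 regions, and 107 and 598. Peaks numbered 15632 ± 4586 (SD, n = 2) in stimulated and 10456 ± 361 (SD, n = 2) in vehicle cells (exact permutation p = 0.333, the smallest possible). Stimulated replicate 2 stood apart with 18875 peaks against 12389 in replicate 1, whose treatment characteristic reads vehicle, at 19014659 and 19266013 fragments. Both vehicle libraries were shallower, at 18063278 and 16033515 fragments for replicates 1 and 2. Depth thus ran with treatment in the direction of the gains, and its part in them was not tested. With lists of equal length, which draw both directions towards balance, the counts became 1174 gained and 867 lost, and without stimulated replicate 1 or replicate 2 the gained regions numbered 8390 or 3402 and the lost 437 or 1186. Without vehicle replicate 1 or 2, 1144 or 1008 regions were lost.

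**Figure D1:**
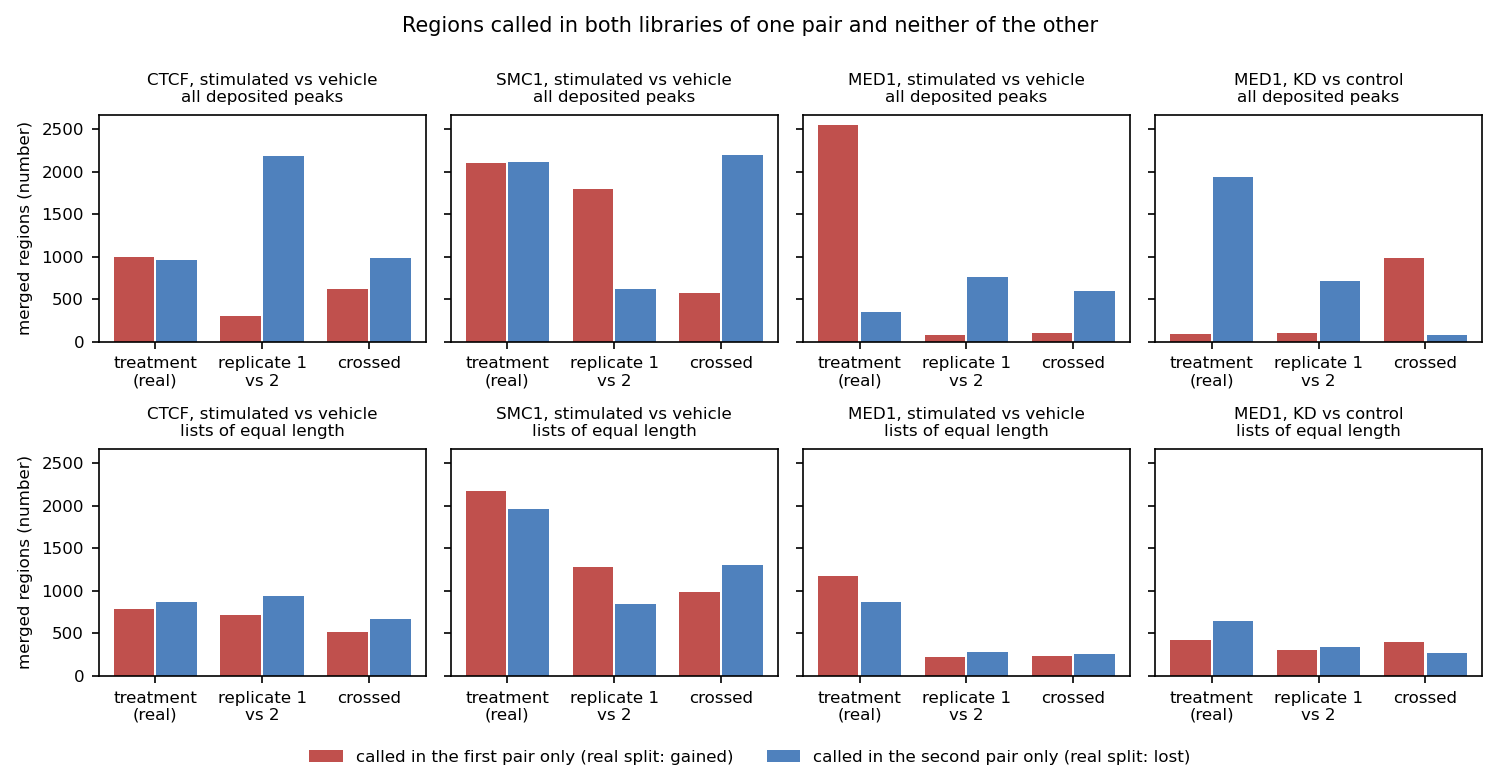
Number of merged regions (y axis) called in both libraries of one pair and in neither of the other, for the treatment split and the other 2 splits of each 4 libraries, with all deposited peaks (top) and with lists of equal length (bottom). For MED1 the treatment split gave 2545 and 353 regions with all peaks and 1174 and 867 with equal lists, where the other splits gave at most 280.

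The strongest gained MED1 regions lay in Adam12, Adcy3, Scp2 and Clstn3 and 34.0 kb from Tle3, a corepressor gene. The strongest lost regions lay in Gucy2f, Hip1 and Kat2b, 36.4 kb from Id3 and 50954 bp from Lrrc28. Gained regions lay within 1 kb of a gene end more often than regions in all 4 libraries, 32.1% against 22.4% (odds ratio 1.64, Fisher's exact test, adjusted p = 3.86e-20), and lost regions less often, 10.5% (odds ratio 0.41, adjusted p = 3.8e-08). CTCF regions had the same order, 246 of 997 gained and 105 of 956 lost against 6018 of 36639 (odds ratios 1.67 and 0.63, Fisher's exact test, adjusted p = 1.61e-10 and 3.42e-06), and SMC1 regions did not, with 17.5% and 9.4% against 21.9% (odds ratios 0.76 and 0.37, adjusted p = 2.65e-06 and 1.1e-48). These gene-end shares were not compared at like strength. The CTCF order arose although CTCF calls differed by treatment in no larger number than by replicate number. The densest clusters of MED1 regions in stimulated cells spanned Dnajb12 and Ddit4 with 13 regions, and a stretch near Irs2, a stretch near Tle3, a stretch over Gpx4, Sbno2 and Stk11, and one in Chst11 with 12 each. In vehicle cells the densest had 16 regions and no protein-coding gene within it, and the next were at Chst11, at Lhpp and Fam53b, at Kcnk3 and at Frmd8.

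Gene lists fixed in advance were tested for more or fewer gained regions than matched genes. Of 112 tests none passed after adjustment, the smallest adjusted p being 0.125, and 9 had an unadjusted permutation p under 0.05 where chance gives 5.6. Under other settings 0 to 6 of the 112 passed. The cAMP and beta-adrenergic list came nearest for MED1: 54 gained regions at 24 genes against 32.3 expected (permutation p = 0.0025, adjusted p = 0.125; 0.03 at −log10 q of 5). The thermogenic list had 19 gained MED1 regions at 16 genes against 21.9 expected (permutation test, adjusted p = 1), and with equal-length lists its ratio of 0.87 became 1.11. Adipocyte identity genes had 16 against 30.7 (permutation test, adjusted p = 0.28; 0.027 with every gene within 50 kb), lipolysis and fatty acid oxidation 11 against 20.3 (adjusted p = 0.575) and circadian clock genes 2 against 7.9 (adjusted p = 0.462). With the replicate block the adipocyte identity and lipolysis lists passed (ratios 0.6 and 0.52, permutation test, adjusted p = 0.042 and 0.038). The block uses a looser rule of gain, since it also counts regions gained in 1 numbered pair only. Gained MED1 regions numbered 13 against 14.3 for glucose and glycolysis, 6 against 8.0 for oxidative phosphorylation, 6 against 5.9 for looping, Mediator and H2A.Z machinery, and 5 against 4.9 for housekeeping genes. They numbered 2 against 4.8 for inflammatory genes and 4 against 5.7 for preadipocyte and fibroblast markers. Markers of other cell types had few MED1 regions of any kind, 1 for macrophages, 1 for skeletal muscle and 6 for the neuronal reference.

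Cohesin calls were gained and lost in like numbers between the libraries titled stimulated and vehicle. The characteristics of all 4 SMC1 libraries contradict these titles and would make them stimulated H2A.Z KD and stimulated control cells, so the SMC1 directions rest on the titles. SMC1 regions gained numbered 2098 and those lost 2113, against 35229 in all 4 libraries. Ppargc1a had 2 gained and 2 lost, Pde4d 3 and 2, Vegfa 2 and 2, Hk2 2 and 1, and Prkar2b 1 and 1, while Zfp516 and Pde4b had 3 gained each and Fosl2 2. Creb3l1 and Me1 had 2 lost each. Ucp1 had 1 gained SMC1 region, at chromosome 8, 83291139 to 83291545, inside the gene, and Pparg 2 gained and 1 lost. Cidea, Prdm16 and Adipoq had 1 lost each, and Dio2, Elovl3, Adrb3 and Fabp4 had neither. The Ucp1 region was not gained at −log10 q of 3 or 5, with equal-length lists or with summit windows, whereas with 50% cover Ucp1 had 3 gained. The lost regions of Prdm16, Adipoq and Hk2 were not so classed at −log10 q of 3, nor that of Pparg with equal-length lists or its gained regions with summit windows. In the other direction, lost regions numbered 3 at Pparg and 2 at Hk2 with summit windows, and 2 at Prdm16 with 50% cover. Single gained regions appeared at Elovl3 and Adipoq with 50% cover and at Cidea and Fabp4 with summit windows. A lost one appeared at Zfp516 with summit windows, and its gained regions numbered 1 in place of 3 at −log10 q of 5. The strongest gained regions lay near or in Stambpl1, Ugt8a, Pkd1l1, Bmp6 and Atf7ip, and the strongest lost near or in Lonrf2, Nav3, Rspo2, Csl and Wdr7.

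The other splits of the SMC1 libraries gave 1802 and 626, and 573 and 2192, so that a single direction was matched by another split, and SMC1 peaks numbered 53070 ± 1759 and 53178 ± 6015 (SD, n = 2, exact permutation p = 1.0). With lists of equal length 2175 were gained and 1966 lost, where the other splits reached 1301. Leaving out 1 library at a time gave 3043 to 6432 gained and 4016 to 8151 lost. The cAMP list had 33 gained SMC1 regions against 16.6 expected (permutation p = 0.00118, adjusted p = 0.125) and 13 lost against 17.7. With equal-length lists the former became 39 against 17.2 (permutation test, adjusted p = 0.0045). Glucose and glycolysis genes had 18 gained against 7.6 (ratio 2.36, permutation test, adjusted p = 0.125), but the ratio was 0.99 at −log10 q of 5 and passed with every gene within 50 kb (2.26, adjusted p = 0.027). Adipocyte identity genes had 5 lost against 15.7 (ratio 0.32, permutation test, adjusted p = 0.125), and the ratio was 0.59 with the replicate block (adjusted p = 0.042) and 0.92 without replicate 2.

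CTCF calls differed between vehicle and stimulated cells in no larger number than between the replicate numbers, though in a larger number than in the crossed split. Ucp1, Dio2, Elovl3, Prdm16, Adrb3, Fabp4 and Adipoq had no gained or lost CTCF region, except that Adipoq had 1 lost with equal-length lists. Cidea had 1 gained, Pparg 1 of each, and Ppargc1a and Myod1 1 lost. Of the cAMP and thermogenic lists, Pde10a had 2 gained, Vegfa 2 lost and Ppargc1b 1 of each. Sik1, Pde4d, Angptl4 and Cpt1b had 1 gained and Kdm3a and Sik2 1 lost. With equal-length lists the gained region of Cidea, absent also at −log10 q of 5, and the lost regions of Pparg, Vegfa, Ppargc1b and Sik2 were no longer so classed, and Pde4d had 1 lost. Ppargc1a had 1 gained with 50% cover. The strongest gained regions lay in Nubpl and near Thsd7a, St8sia1, Jade1 and Gm14037, and the strongest lost in Bmerb1, Fmnl2, Arhgap10 and Arl15 and near Timd2. CTCF peaks numbered 46821 ± 5023 in stimulated and 46848 ± 2848 in vehicle cells (SD, n = 2, exact permutation p = 1.0). Gained regions numbered 997 and lost regions 956, against 36639 in all 4 libraries, where the split by replicate number gave 299 and 2190 and the crossed split 620 and 984. With lists of equal length the sums of both directions were 1658 for treatment, 1662 for replicate number and 1190 for the crossed split. CTCF libraries of the same replicate number shared 77.5% and 78.5% of regions called in either, and crossed numbers 76.2% and 76.9%. The 2 stimulated libraries shared 75.8% and the 2 vehicle libraries 78.5%. Fragment sizes also went by number, 244 and 243 bp for replicate 1 against 230 and 229 bp for replicate 2. So did depth, at 16222468 (stimulated) and 18691427 (vehicle) fragments for replicate 1 against 24120395 and 23189844 for replicate 2. The cause was not tested. Leaving out 1 library at a time gave 1651 to 5052 gained and 1440 to 4013 lost.

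Most Mediator regions carried cohesin and most lacked CTCF. In stimulated cells 87.3% of 10611 MED1 regions overlapped SMC1 and 21.2% overlapped CTCF, and in vehicle cells 89.8% and 19.5% of 7709. SMC1 overlapped CTCF at 57.3% of its regions in stimulated and 59.8% in vehicle cells. CTCF chromatin was fixed without DSG and had inputs of its own, whereas SMC1 and MED1 shared fixation and control inputs. The higher overlap of MED1 with SMC1 than with CTCF therefore cannot be told apart from these differences in preparation. SMC1 regions gained at stimulation carried CTCF at 14.9%, against 64.2% of regions in all 4 libraries (odds ratio 0.10 by Fisher's exact test, with a p too small to be represented), and 34.4% of those lost did (odds ratio 0.29). For gained regions the odds ratio was 0.15 or 0.22 within a single replicate number and 0.47 at like strength, an alternative added after seeing the data. MED1 gained regions carried SMC1 at 77.1%, against 92.2% (odds ratio 0.29, Fisher's exact test, adjusted p = 1.64e-77), and lost regions at 79.3%, against 91.6% (odds ratio 0.35, adjusted p = 6.26e-12). For gained regions that odds ratio was 0.47 at like strength and 0.50 with summit windows.

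Places of Mediator gain were enriched for places of cohesin gain, with both taken from the titles. Of 2545 gained MED1 regions, 227 (8.9%) overlapped a gained SMC1 region, against 130 of 10799 other MED1 regions called in 2 or more of the 4 libraries (1.2%; odds ratio 8.04, Fisher's exact test, adjusted p = 4.09e-78). MED1 gained regions overlapped lost SMC1 regions less often than other MED1 regions did (odds ratio 0.27, Fisher's exact test, adjusted p = 1.15e-05), and MED1 lost regions overlapped lost SMC1 regions more often (odds ratio 10.13, adjusted p = 2.27e-18). Within a single replicate number the odds ratio of gain with gain was 4.69 or 3.62. Most gained MED1 regions thus had no gained SMC1 call, and at the gained Adcy3 region all 4 SMC1 libraries had a peak.

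In stimulated H2A.Z KD cells MED1 was uncalled at regions that control cells called, some of them at thermogenic and lipid genes, whose lists had no excess. Ppargc1a and Prkar2b, a regulatory subunit of protein kinase A, had 3 lost regions each. Prdm16, Fabp3, Cebpb, Ppargc1b, Ebf2, Kcnk3 and Pde4d had 2 each, and Pparg and Adipoq had 1. Cpt1b, which carries fatty acids into mitochondria, held the strongest lost region, at chromosome 15, 89418382 to 89419089, inside the gene; vehicle replicate 2 also called it. The next strongest lay in Mideas and Pde4dip, 36.8 kb from Rgma and 101.4 kb from Cachd1. The MED1 region of Ucp1 was called in both KD libraries, and Elovl3, Cidea, Adrb3 and Fabp4 had none lost. At −log10 q of 5 Pde4d had none lost, Prdm16, Cebpb and Ebf2 1 each, and Cidea 1, and with 50% cover Adrb3 had 1. With summit windows regions gained in KD cells appeared, 2 each at Ucp1 and Cebpb and 1 each at Ppargc1a, Pparg and Adipoq. Pparg also had 1 gained with equal-length lists. The strongest of the few regions called in KD cells only lay in Aig1, Wwox, Laptm4a and Pacsin2 and 20.4 kb from Mrps6.

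In all, 1935 MED1 regions were lost in KD against stimulated control cells and 92 gained, with 6436 called in all 4 libraries. The other splits gave 108 and 710, and 986 and 86. KD libraries listed 10306 ± 544 peaks (SD, n = 2) against 15632 ± 4586 (exact permutation p = 0.333, the smallest possible). With lists of equal length 646 were lost and 419 gained, where the other splits reached 396. Leaving out stimulated control replicate 1 gave 7765 lost regions and leaving out KD replicate 1 gave 3231. The 92 gained became 543 and 621 without KD replicate 1 and 2, and 607 without stimulated control replicate 2. Thermogenic genes had 19 lost regions against 18.7 expected and cAMP genes 22 against 26.6 (permutation test, both adjusted p = 1). Lost regions lay within 1 kb of a gene end at 29.4%, against 23.8% (odds ratio 1.33, Fisher's exact test, adjusted p = 1.7e-06), a comparison not made at like strength. The densest clusters in KD cells lay at Noct with 11 regions, and with 10 each at Abca1, near Tomm20, near Cebpb and on chromosome 16 from 24156733.

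Of the 2545 stimulus-gained MED1 regions, 1059 (41.6%) were called in neither KD library, 749 in 1 and 737 in both, whereas 6.7% of regions called in both stimulated and both vehicle libraries were called in neither. The 5 strongest gained regions, including that of Adcy3, were called in both KD libraries. At like strength 856.3 uncalled regions were expected, so that the observed number was 1.24 times as high (permutation p = 2e-05, the smallest the resamples can give). Strength read with error can give such a value alone: in a simulation without any KD effect the ratio averaged 1.25. The error and the rate of uncalled regions were set by hand there, not estimated from these libraries. The simulation therefore shows that such a value can arise, not how much of the real one did. Both comparisons use the same stimulated control libraries, and part of their overlap may come from these. It was 1059, against 467.8 for independent lists among the 10526 regions that both stimulated libraries called and 220.3 for independent lists among all 22358. Unchanged groups in simulation gave 68.0, from simulated sets of 441.5 and 441.4 regions. These sets are well under the real 2545 and 1935, so 68.0 does not measure how much of the 1059 the shared libraries made.

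**Figure D2:**
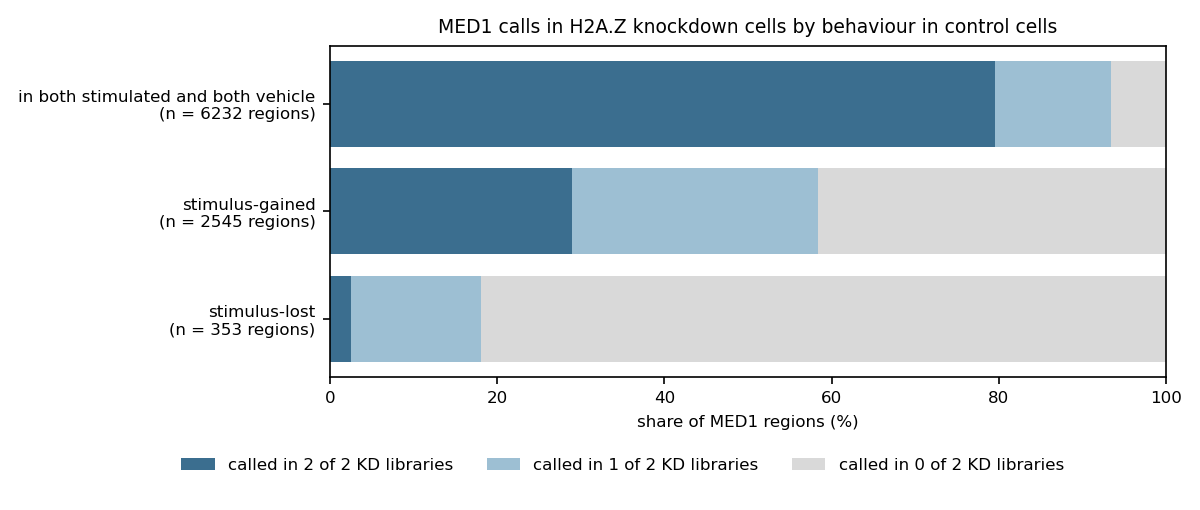
Share of MED1 regions (x axis, percent) called in 2, 1 or 0 of the 2 H2A.Z KD libraries, for regions called in both stimulated and both vehicle control libraries, gained at stimulation or lost at stimulation. Regions called in neither KD library made up 6.7%, 41.6% and 81.9% of these classes.

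**Figure D3:**
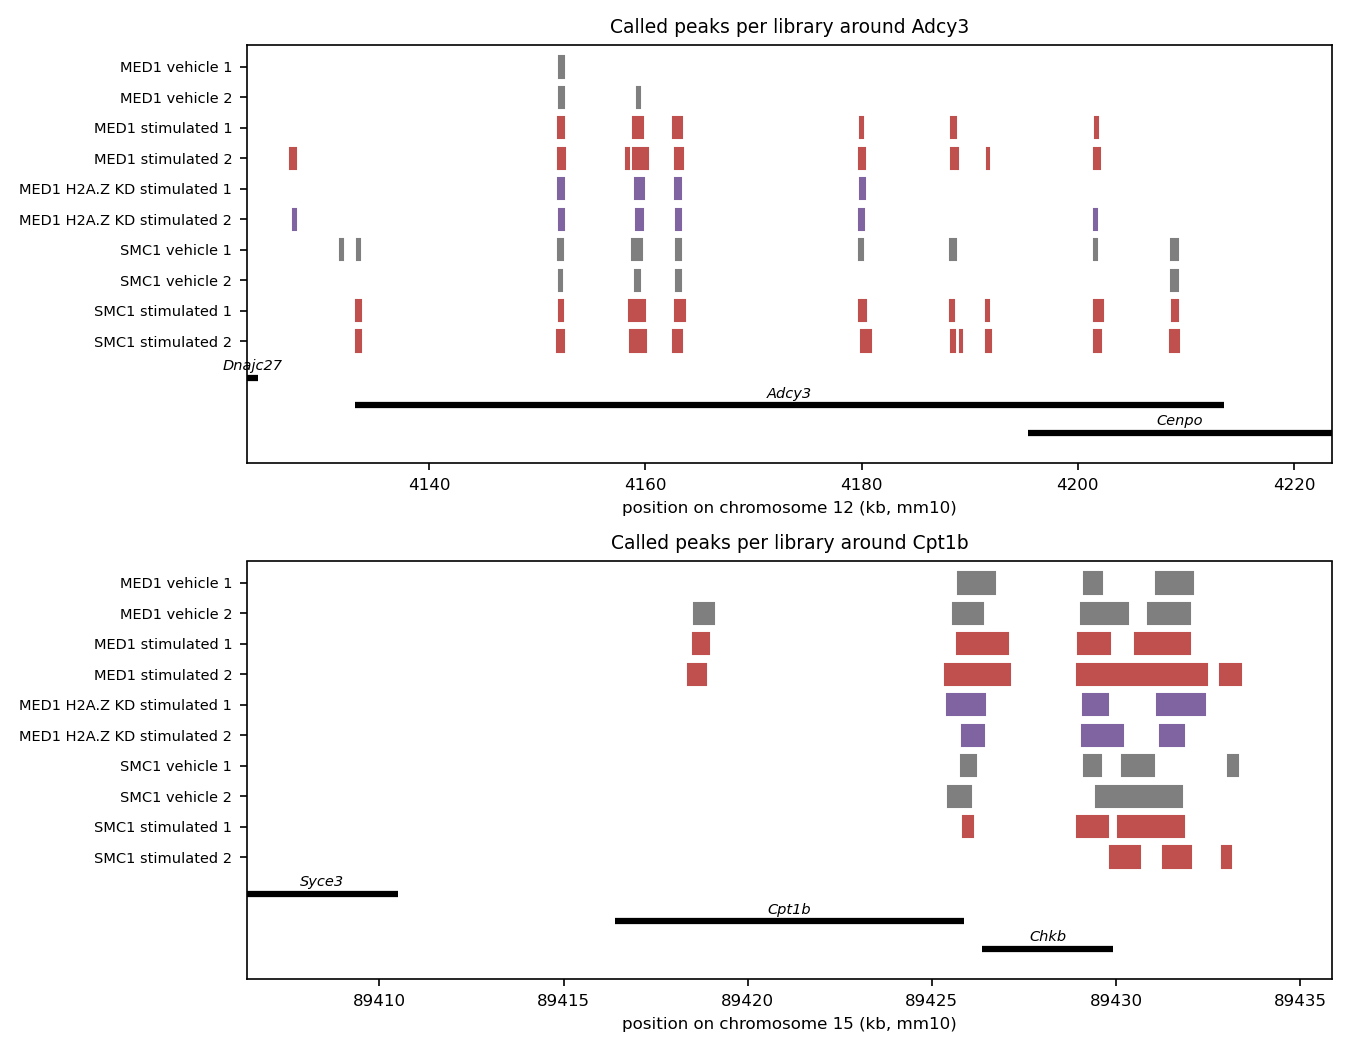
Peaks called in each MED1 and SMC1 library (rows; position in kb on mm10 on the x axis) around Adcy3 and Cpt1b, with gene spans as black bars. The MED1 region of Adcy3 that starts at 4162577 is present in stimulated and KD libraries and absent from both vehicle libraries, and the Cpt1b region that starts at 89418382 is absent from both KD libraries.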

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

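Peaks on the mitochondrial chromosome entered no comparison. Both vehicle MED1 libraries had 0 such peaks, while H2A.Z KD replicate 1 had 4, KD replicate 2 had 1 and stimulated control replicate 1 had 1. Stimulated control replicate 2 also had 0, so these few peaks did not separate the stimulated control group from vehicle. No explanation was tested.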

How the results depend on the processing

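Alternatives added after seeing the data were peaks that cover 50% of a region, the nearest gene end, and odds ratios at like strength. Overlap and KD results kept their direction and side of the threshold under all alternatives run, with odds ratios of 0.08 to 0.47 for SMC1 gained with CTCF, 0.26 to 0.50 for MED1 gained with SMC1, 3.62 to 9.98 for gain with gain, and ratios of 1.08 to 1.48 for KD. Gained and lost counts stayed within 1.5 times under the stricter q thresholds, 50% cover and summit windows, except that KD-gained regions numbered 61 in place of 92 at −log10 q of 5 and numbered 214 with summit windows. Lists of equal length gave 1174 gained and 867 lost for MED1 at stimulation and 419 gained and 646 lost for KD, by construction from fewer peaks. Leaving out 1 library, which loosens the rule for its group, gave 1651 to 5052 gained and 1440 to 4013 lost for CTCF, 3043 to 6432 and 4016 to 8151 for SMC1, 3276 to 8390 and 437 to 1186 for MED1, and 131 to 621 and 2794 to 7765 for KD. The SMC1 peak ratio of 0.998 turned to 1.004 and 1.008 at −log10 q of 3 and 5, well within the spread of the libraries. For the cAMP list, SMC1 gains passed the adjusted threshold at −log10 q of 5 (2.44 times expected), with equal lists (2.27), 50% cover (2.9), genes within 1 Mb (2.14), without replicate 2 (1.81) and with the replicate block (1.61); without replicate 1 the ratio was 1.46. MED1 gains of that list passed at −log10 q of 5 (1.8), with 50% cover (1.81) and with every gene within 50 kb (1.65). With equal lists they lay at the threshold (2.04, adjusted p = 0.054), and 10 further random draws gave adjusted permutation p of 0.043 to 0.068, 2 of them under 0.05, so that setting is not counted as a call; for SMC1 all 10 passed. The KD-lost ratio of 0.83 of that list turned to 1.18 with 50% cover and 1.04 within 1 Mb. The thermogenic ratio of MED1 gains, 0.87, turned to 1.11 with equal lists, 1.06 with 50% cover, 1.03 with summit windows and 1.02 without replicate 2, against 0.96 without replicate 1. Its KD-lost ratio of 1.02 turned to 0.97 at −log10 q of 3, 0.99 by nearest gene end, 0.94 and 0.92 without replicate 1 and 2, and 0.93 with the replicate block. Thermogenic SMC1 gains passed without replicate 2 (1.78; 1.43 without replicate 1). Glucose SMC1 gains (2.36) turned to 0.99 at −log10 q of 5, and passed with every gene within 50 kb (2.26) and without replicate 2 (1.89; 1.22 without replicate 1). In all, 6 of the 112 list tests passed with the replicate block, 4 without replicate 2 and 3 with every gene within 50 kb. Those not yet named were, with the block, fewer MED1 gains at adipocyte identity (0.6) and lipolysis genes (0.52), fewer SMC1 losses at adipocyte identity genes (0.59), fewer MED1 losses at lipolysis genes (0.1) and fewer KD losses at glucose genes (0.55), without replicate 2 fewer MED1 losses at lipolysis genes (0.25), and with every gene within 50 kb fewer MED1 gains at adipocyte identity genes (0.46). The cause was not tested for these lists. Same-number deviations hardly correlated (−0.01 to 0.04), but CTCF calls split by replicate number. With the replicate block the overlap odds ratios were 0.18, 0.30 and 4.12 and the KD ratio 1.13. Gained and lost counts have no separate block value, since a region called in both libraries or neither is alike in each numbered pair. Other results, named genes included, gave 375 values alike, 98 that moved by over 1.5 times, 10 that newly passed (the 9 of lists above, and KD-gained regions within 2.5 kb of a gene end, odds ratio 1.73) and 1 that reversed. Single-gene counts moved readily: of 337 values of named genes under the peak and region settings 95 moved, 25 of them to 0 and 22 from 0. Clusters of 5 or more regions fell from 190 to 47 in stimulated cells when joined within 5 kb. Motif alternatives were not run. Depth limits all of this: a weak peak can miss a list by enrichment alone.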

Other observations

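Of the 353 regions that lost MED1 at stimulation, 289 (81.9%) were called in neither KD library. They were chosen as uncalled in both stimulated control libraries and the KD cells were stimulated too, so this share says nothing about the KD. Genes chosen after their values were seen include Tle3 with 7 gained MED1 regions, Scp2 with 6 and Acsl1 with 5, and for KD-lost regions Gse1 and Rreb1 with 5 each and Lpin1 with 4. For SMC1, Trib1 had 6 gained regions, Nfia 5 and Hilpda 4.

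The tests of list length for MED1 gain, of weak regions and of strength were chosen only after the result was seen, whereas those across replicate numbers and of KD list length were written before it. MED1 gains outnumbered losses in the lists as deposited. Whether longer stimulated lists or a net increase lies behind this cannot be told apart: with equal lengths the ratio of gained to lost regions was 1.35, but lists of one length draw gains and losses towards balance whatever the cause. Longer lists do not account for the presence of treatment-specific regions, which at equal length were 4.08 times as many in sum as in the highest other split. With 3 splits a share under 0.05 cannot be reached. No biological explanation was tested.

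MED1 and SMC1 gains coincided, and libraries of the same replicate number shared an input. With SMC1 gains from 1 replicate number and MED1 gains from the other, the lower odds ratio was 3.1 (95% interval 2.79 to 3.44), and the other was 3.47, so a shared input cannot be the whole cause. Within 1 replicate number the values were 4.69 and 3.62, of which only the first lies clearly above those across numbers, so a part is not settled. Weak regions that drift in and out of lists would raise the overlap of MED1 gains with SMC1 losses too, and that odds ratio was 0.27. No biological explanation was tested, and the direction of the SMC1 calls rests on titles that the characteristics contradict.

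Stimulus-gained MED1 regions were uncalled in KD cells more often than others of like strength. With lists of equal length the ratio was 1.48, so the excess did not need shorter KD lists. Strength read with error could hold that ratio above 1 as well, so list length is not excluded as a part of the 1.24. Lower strength stays open: the ratio of 1.24 was 1.08 without replicate 1. A simulation in which strength was read with error, of a size set by hand, averaged 1.25 with no KD effect. A need for H2A.Z at these regions, which the design was built to examine, can therefore not be told apart from their lower strength with peak lists alone.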
